A study of Mus musculus with 13 samples.

How the data were processed

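Genomic DNA of 11 spontaneously transformed mouse epithelial cultures, 5 from bladder and 6 from kidney, was hybridised with sex-matched normal liver DNA on 13 Agilent 2-colour arrays, 1 array per culture on a smaller design and a second array of bladder culture M2C and kidney culture M2G on a larger design. Samples were grouped by the tissue given in the labels, with sex, passage and dye taken from the labels too. Per the file headers the scans were quantified with Agilent Feature Extraction, version 8.1.1.1 on 6 arrays, 9.1.1.1 on 1, 9.1.3.1 on 4 and 9.5.1.1 on the 2 larger arrays, with spatial detrending, background subtraction and linear dye normalisation. The deposited files give processed intensity and raw mean and background intensity per spot and channel, and a log10 ratio of red over green, which per the file headers and the values equals the ratio of the processed signals. The authors' deposited table for the 2 larger arrays holds log2 values for 65493 probes, with medians of 0.02 for bladder M2C at passage 59 and 0.13 for kidney M2G at passage 35. Its direction matched culture over reference (r = 0.69 and 0.87 with the ratios computed here), its slopes were 0.50 and 0.78, its scale and centring are unknown, and it was not used further. The genome build is not given in the sources used here, and the 2 designs place the same probes at different positions, so coordinates are those of each array's own file.

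The labels disagree on the dyes: each sample's label gives Cy5 to the culture DNA on 6 arrays and Cy3 on the others, while the labelling protocol names Cy3 for all culture DNA. The choice was checked with kidney culture M2G, whose 2 arrays carry opposite dyes by the sample labels. Turned by those labels, they correlated at r = 0.79 over 41481 shared probes, so the sample labels were used for every array. This checks 1 of the 6 Cy5 arrays directly. A further check, added after seeing the data, used the X chromosome signal minus the autosomal signal within a channel, which in the reference DNA of the Cy3 arrays lay between -0.97 and -0.93 for males and near -0.03 for females. On 5 of the 6 Cy5 arrays, kidney M2G among them, the channel labelled reference lay within 0.06 of those values and the channel labelled culture at least 0.19 away, as the labels require. On kidney M2C the order was the other way (0.072 and 0.026), so this check did not bear out its label. Its 4-probe region over Cdkn2a (-5.00) had 2 probes not well above background in the channel labelled culture. Turned dyes would place that loss in the normal liver DNA, which argues for the label. With all 6 turned 0 chromosomes were gained and 0 lost. The 2 arrays of bladder M2C, of 1 dye, correlated at r = 0.69 over 41511 probes. Among the 11 arrays of the smaller design, the lowest correlation over all probes between arrays of 1 dye orientation was -0.03, and between arrays of opposite orientation correlations ran from -0.26 to 0.60.

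From the processed signals the log2 ratio of culture over reference was computed. Control spots, spots marked as non-uniform or as population outliers and spots whose reference signal was not well above background were left out, spots of a probe were averaged, and each array was centred on the median of its autosomal probes, with no loess or quantile step. A chromosome's value is the median of its probes, and a chromosome was called gained or lost in a culture at 0.2 in size. Probes were named by the gene name or accession in the files, updated through a RefSeq gene table of assembly GRCm38.p6 used only for names, and kept where the position relative to neighbouring probes fitted within 1 megabase; 29950 of 42090 placed probes received a name, for 16519 genes, of which 16480 were measured on all 11 arrays. A gene's value is the mean of its probes. Segments came from circular binary segmentation with a threshold of 5 on the statistic and at least 3 probes.

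Means over cultures were tested against 0 by exact sign-flip permutation (2048 flips), tissues and sexes by exact permutation of the cultures (462 splits for tissue, and 150 within dye), all two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, tissue means with a shared spread). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures matplotlib 3.10.9. The tests, the 9 gene lists and 4 list differences were fixed before the data were examined. Named genes were, by a rule of that time, the 5 list genes with the largest change in each direction among those past the threshold, every list gene inside a high-level region, and always Myc, Mdm2, Cdkn2a, Cdkn2b, Trp53, Cdh1, Vim and Zeb1. Further list members, and non-list genes named in regions, were chosen as examples after their values were seen. The planned correlation of burden with passage over all cultures and within kidney was replaced by that within the later cluster, because passages fall into 2 clusters.

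The procedures were tested on simulated data. With 200 genes changed among 16480, limma's test against 0 found 73.1% of changes of 0.5 and 100% of changes of 1 on the log2 scale, and its test between tissues found 11.9% of changes of 0.5 and 73.1% of changes of 1. The simulated genes were independent of each other, while in the data genes of a chromosome move together, so these rates need not hold there. The exact tests gave p under 0.05 for 5.9% (sign flip) and 5.8% (permutation) of 1000 unchanged items. Segmentation found 95% of 200-probe changes of 0.3 at a noise of 0.2.

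Alternatives were normexp background correction with an offset of 50, centring on the density peak, a stricter and no spot filter, chromosome means, gene medians, calls at 0.1 and 0.3, segmentation thresholds of 4 and 7, at least 5 probes, the second arrays, dye, sex, tissue or shared culture code as a block, array weights, each culture left out, and Cy3 as the culture dye throughout, as the protocol text says. Leaving out the 3 arrays with noise above 0.4, the dye block for the gene lists and for the number of changed chromosomes, the gene lists without Cdkn2a, Myc and Mdm2, and the turned dyes for the cultures with a change in these genes, were added after seeing the data.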

Results

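DNA copy number was measured by array comparative genomic hybridisation in epithelial cultures from the bladder and kidney of C57BL/6 mice that had transformed spontaneously in culture. On each 2-colour oligonucleotide array the DNA of a culture competed with normal liver DNA from mice of the same strain and sex. The series held 13 arrays of 11 cultures, 5 from bladder (3 male and 2 female, passages 53 to 67) and 6 from kidney (3 male and 3 female, passages 35 to 55). Bladder culture M2C and kidney culture M2G each had a second array of a larger design, which was kept out of the tests. The 11 arrays of the smaller design had between 42350 and 42400 usable probes. Median signal over background was between 4.92 and 12.7 for the culture DNA and between 5.80 and 9.99 for the reference. Probe noise, the SD around the local level, was between 0.14 and 0.27 on the log2 scale on 8 arrays and higher on bladder M1C (0.64), kidney M2C (0.51) and kidney F1G (0.47). Part of this spread was a pattern shared by bladder M1C and kidney M2C, which correlated at 0.91 after the local level was removed. Values are log2 ratios of culture over liver DNA, so a negative value is a loss relative to the median autosomal probe of that array and not an absolute copy number. The number of arrays limits the precision. The labels do not say whether the cultures came from separate animals, and 4 culture codes occur in both tissues. The p-values therefore measure the spread between these cultures, and a test against 0 leaves out the spread of the reference DNA.

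Which chromosomes were gained or lost relative to normal liver DNA was asked over all 11 transformed cultures. No untransformed culture was measured, so the time of a change is not known. Chromosomes 5, 10, 11, 15, 17 and 19 were gained, and chromosomes 4, 7, 9, 12, 13, 14 and 18 were lost. Chromosome 19 had the largest mean gain, 0.32 ± 0.27 (SD, n = 11), followed by chromosome 15, which carries the Myc oncogene, at 0.27 ± 0.18, and chromosome 5 at 0.27 ± 0.17. Chromosome 4, which carries the cell cycle inhibitor gene Cdkn2a, had the largest mean loss, -0.37 ± 0.29, followed by chromosome 12 at -0.31 ± 0.25 and chromosome 9 at -0.27 ± 0.19. Chromosome 5 lay above 0 in 11 of 11 cultures and chromosome 9 below 0 in 11 of 11. At a threshold of 0.2 in a single culture, chromosomes 15 and 19 were each gained in 8 cultures, chromosome 12 was lost in 8 and chromosome 4 in 7. These counts depend on the zero point of each array. Centred on the peak of the probe density, bladder F2G moved from 0.27 to 0.006 on chromosome 15 and from 0.24 to -0.03 on chromosome 19. Bladder F1G moved from 0.09 to -0.05 on chromosome 5, and kidney F1G from -0.01 to 0.001 on chromosome 9. In the other direction, bladder M1C became lost on chromosomes 4 (-0.25) and 12 (-0.24).

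In the exact sign-flip permutation test over cultures, two-sided and adjusted over 20 chromosomes, 6 chromosomes passed as gained and 7 as lost. The adjusted p was 0.0078 for chromosomes 5, 9, 12, 15 and 17, 0.0084 for chromosomes 4 and 11, 0.0098 for chromosomes 13, 18 and 19, and 0.016 for chromosomes 7 and 14. The smaller means were 0.21 ± 0.13 for chromosome 11, 0.21 ± 0.10 for chromosome 17, -0.26 ± 0.23 for chromosome 13, -0.24 ± 0.26 for chromosome 14, -0.14 ± 0.14 for chromosome 18 and -0.12 ± 0.11 for chromosome 7. Chromosome 10, at 0.21 ± 0.30, was the weakest call (permutation test, adjusted p = 0.041), and it did not pass when the arrays were centred on the peak of the probe density (adjusted p = 0.18) or when any of 7 single cultures was left out. Chromosome 7 did not pass with another background correction (-0.08, adjusted p = 0.063), and chromosome 6 passed as a loss with density centring (-0.06, adjusted p = 0.0065). Dye and scan series, here defined by the Feature Extraction version, went together. The culture DNA carried Cy5 on 6 of these arrays (version 8.1.1.1) and Cy3 on 5 (version 9.1.1.1 or 9.1.3.1). Bladder M2C of the Cy3 set was scanned on another day than the other arrays of that set. All 13 chromosomes had the same sign of the mean in both sets, as had 16 of all 20. The 13 were selected on the mean over both sets, so their agreement is no independent check. With dye as a block the 13 calls passed and chromosome 1 passed as a gain (adjusted p = 0.049), as it did without bladder M1C (0.025), while within a set the exact test cannot go below 0.031 for 6 arrays or 0.0625 for 5, before adjustment.

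**Figure D1:**
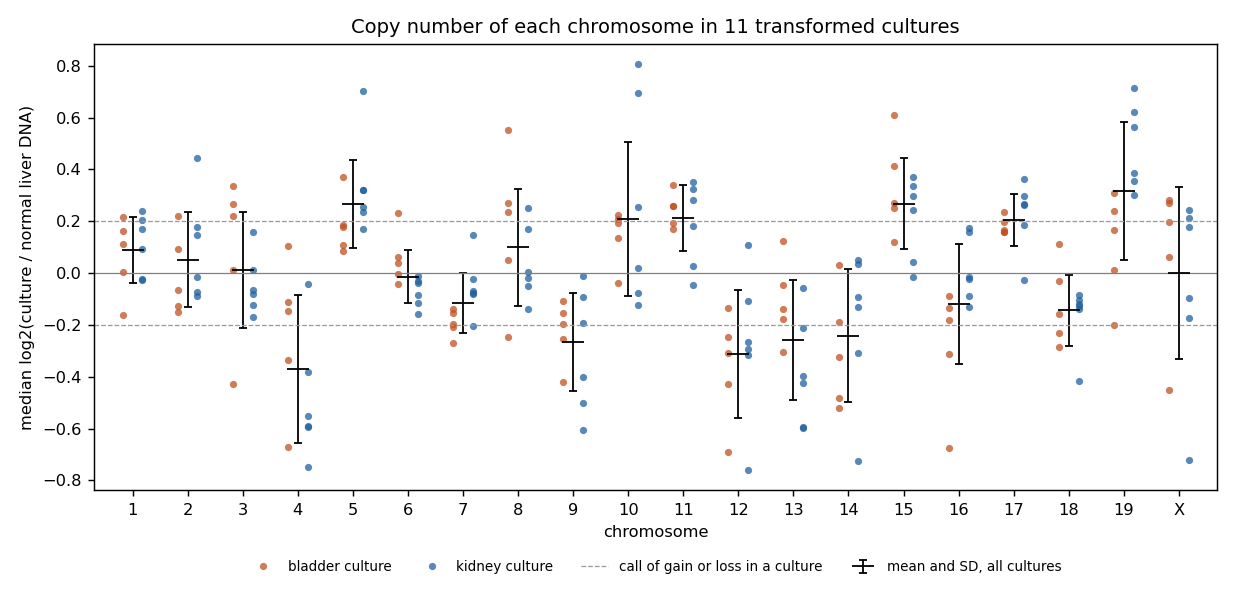
Median log2 ratio of each chromosome (vertical axis) by chromosome (horizontal axis) in the 5 bladder and 6 kidney cultures, 1 point per culture, with the mean and SD over the 11 cultures in black and dashed lines at 0.2 above and below 0. Chromosome 9 lies below 0 and chromosome 5 above 0 in all 11 cultures, and chromosome 19 averages 0.49 in kidney and 0.11 in bladder cultures.

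Whether bladder and kidney cultures differed was tested for each chromosome. Chromosome 19 averaged 0.11 ± 0.20 (SD, n = 5) in bladder and 0.49 ± 0.17 (n = 6) in kidney cultures, and it was gained in 6 of 6 kidney and 2 of 5 bladder cultures. Of the bladder cultures counted, F2G (0.24) stood at -0.03 with density centring. Chromosome 16 averaged -0.28 ± 0.24 in bladder and 0.01 ± 0.13 in kidney cultures. Neither difference passed after adjustment. No chromosome differed between the tissues by the exact permutation test over 20 chromosomes (0 passed, lowest adjusted p = 0.108), and 5 had an unadjusted p under 0.05, namely 6, 7, 13, 16 and 19. For chromosome 19 the difference of -0.38 (exact permutation p = 0.0065) was -0.18 within the Cy5 arrays, -0.62 within the Cy3 arrays and -0.39 with dye as a block, and with that block the lowest adjusted p over chromosomes was 0.178. The tissue also goes with passage, since 5 of 6 kidney cultures were at passage 41 or below and the bladder cultures at 53 or above. Some alternatives made calls: chromosome 19 passed with another background correction (adjusted p = 0.043), chromosomes 7, 16 and 19 with density centring, 6 and 19 with the second arrays in place of the first, and 16 and 19 without bladder culture M1I.

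Male and female cultures were each compared with a reference of their own sex. Chromosome 11 averaged 0.29 ± 0.07 (SD, n = 6) in male and 0.12 ± 0.13 (n = 5) in female cultures, with differences of 0.31 within the Cy5 arrays and 0.06 within the Cy3 arrays. This was the lowest p of the 20 chromosomes (exact permutation p = 0.019, adjusted p = 0.390), so 0 chromosomes differed between the sexes and 1 had an unadjusted p under 0.05.

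Among single genes Cdkn2a, whose products p16 and p19Arf restrain the cell cycle and stabilise p53, had the largest mean loss of the listed genes, at -2.51 ± 2.35 (SD, n = 11). The wide SD reflects a mixture: deep deletions in bladder F1G and F2G and in kidney F1G, M2C and M2G, where the gene's 2 probes averaged between -5.57 and -3.36, and values between -1.02 and 0.07 in the other 6 cultures. Ptprd, a receptor tyrosine phosphatase gene on the same chromosome, was lost at -0.74 ± 0.33 and lay below 0 in 11 of 11 cultures, although at -0.04 in bladder F1G. Twist1, a transcription factor gene of epithelial to mesenchymal transition, averaged -0.63 ± 0.61, Dcc -0.61 ± 0.82 and the cyclin gene Ccnd1 -0.50 ± 0.68. The Dcc mean was carried by the noisy arrays of bladder M1C (-2.21) and kidney M2C (-2.11), and the median was -0.30. Ccnd1 was also low on both (-1.15 and -1.72). Because of the pattern that these arrays share, they are not independent values for single genes. Within the Cy3 arrays Dcc averaged -0.16 and Ccnd1 -0.03, against -1.02 and -0.96 within the Cy5 arrays. Myc averaged 1.14 ± 1.93, carried by bladder M1C at 4.91 and bladder M2C at 4.64. The kinase gene Stk11 (0.56 ± 0.48), the spindle checkpoint gene Mad1l1 (0.52 ± 0.18), the separase gene Espl1 (0.51 ± 0.22) and the keratin gene Krt8 (0.50 ± 0.21) were gained. Twist1, Ccnd1, Myc, Stk11 and Krt8 each rested on 1 probe. On the larger design, with 4 probes, Stk11 stood at -0.14 in kidney M2G, against 0.27 on the smaller design. In bladder M2C it stood at 0.21 against 0.36. Stk11 is a listed tumour suppressor and was highest on the noisy array of bladder M1C (1.69). Espl1 and Krt8 lie close together on chromosome 15, so their gains are not independent.

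**Figure D2:**
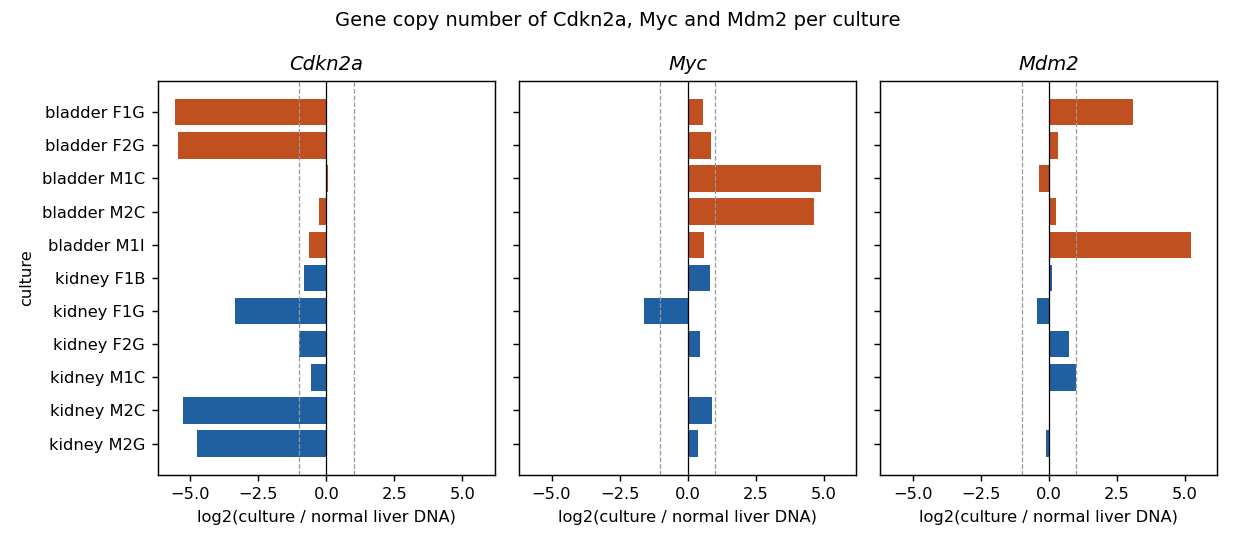
Log2 ratio (horizontal axis) of Cdkn2a, Myc and Mdm2 in each of the 11 cultures (vertical axis, bladder in orange and kidney in blue), 1 bar per culture from 0, with dashed lines at 1 and -1. Cdkn2a lies at -3.36 or below in 5 cultures, Myc above 4 in bladder M1C and M2C, and Mdm2 at 5.21 in bladder M1I and 3.08 in bladder F1G.

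In limma's moderated test of the mean over both tissues, with Benjamini-Hochberg adjustment over 16480 genes, 2583 genes were gained and 2517 lost. The adjusted p was 0.009 for Cdkn2a, 0.0018 for Ptprd, 0.012 for Twist1, 0.0086 for Stk11, 0.0018 for Mad1l1, 0.0019 for Espl1 and 0.0022 for Krt8. The calls of Myc (limma adjusted p = 0.031), Dcc (0.042), Ccnd1 (0.049) and of the mesenchymal regulator Zeb1 (-0.34 ± 0.40, 0.039) ended when single cultures were left out, 6, 8, 9 and 7 of the 11 respectively. The calls of Myc (0.060) and Ccnd1 (0.075) also ended with another background correction, those of Ccnd1 (0.072), Dcc (0.063) and Zeb1 (0.054) with the second arrays, and all 4 within the Cy3 arrays. Within the Cy5 arrays none of these 11 genes passed (Cdkn2a -1.91, limma adjusted p = 0.088). Without the 3 noisy arrays, an exclusion chosen after the data were seen, Dcc (-0.23), Ccnd1 (-0.31) and Zeb1 (-0.15) did not pass (limma adjusted p = 0.077, 0.095 and 0.097). Mdm2, the ubiquitin ligase gene for p53, averaged 0.90 ± 1.73, carried by bladder M1I and F1G (median 0.27, and means of 0.53 to 1.23 with 1 culture left out), and did not pass (limma adjusted p = 0.073), nor did Trp53 at 0.18 ± 0.23 (0.096), the E-cadherin gene Cdh1 at 0.27 ± 0.36 (0.062) or Vim at 0.15 ± 0.16 (0.115). These depended on the setting: Cdh1 passed as gained with dye as a block (0.26, limma adjusted p = 0.043), Mdm2 (0.020) and Trp53 (0.041) within the Cy3 arrays, and Vim (0.27, 0.041) and Trp53 (0.27, 0.029) with another background correction. Mdm2 (0.016) and Trp53 (0.0081) also passed without the noisy arrays, and Cdh1 (0.038), Mdm2 (0.046) and Trp53 (0.0072) with array weights. With 1 culture left out Cdh1 passed without bladder F1G (0.35, limma adjusted p = 0.021) and Mdm2 without bladder M1C (0.027). Trp53 passed without bladder M1C (0.028) or kidney F1G (0.049). Cdkn2b, the neighbour of Cdkn2a, had no named probe on this design. Genes of one chromosome move together and are not independent. The split of gained and lost genes depended on the processing: it was 2800 and 1467 with another background correction and 1541 and 3042 with density centring, which moves only the zero point. With dye as a block 2876 genes were gained and 2799 lost, within the Cy3 arrays 3193 and 3231, and within the Cy5 arrays, which include the 3 noisy ones, 0 and 6.

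Between bladder and kidney 0 genes passed limma's test after adjustment, and 720 had an unadjusted p under 0.05. Myc was 2.16 higher in bladder on the log2 scale (limma adjusted p = 0.999). With dye as a block, and within each dye set, 0 genes passed.

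Genes of known oncogenes, tumour suppressors and human bladder and kidney cancer were grouped in lists fixed before the data were examined, since the study set its mouse cultures beside the human cancers. Over all 16480 genes 2583 were gained and 2517 lost, and the counts of list members were not tested against that share. Of 42 measured oncogenes 6 were gained and 3 lost over all genes tested, and 5 and 2 adjusted over the list alone. Among them Ccnd3 was gained at 0.33 (limma adjusted p = 0.0038), Cdk4 at 0.41 (0.0086) and Cdk6 at 0.27 (0.012), while Jun was lost at -0.34 (0.0094) and the cyclin genes Ccnd2 (0.14, 0.178) and Ccne1 (-0.16, 0.196) did not pass. Ccnd1 and Mycn (-0.36, 0.017) were the other oncogenes lost. Neither oncogene count over all genes tested lay above the share over all genes. Of 33 measured tumour suppressors 8 were lost and 6 gained, and 9 and 7 adjusted over the list alone. Rb1, the retinoblastoma gene, was lost at -0.40 (limma adjusted p = 0.0083) and Fhit at -0.37 (0.0053), but Brca2 was gained at 0.37 (0.0034) and Brca1 at 0.43 (0.0091). Over cultures the oncogenes averaged 0.10 ± 0.11 (SD, n = 11, exact sign-flip permutation test, adjusted p = 0.020, above 0 in 10 of 11) and the tumour suppressors -0.08 ± 0.10 (adjusted p = 0.033, below 0 in 9 of 11), the latter 0.02 with another background correction (adjusted p = 0.425). Without Myc and Mdm2 the oncogenes averaged 0.06 and still passed (exact permutation, adjusted p = 0.039). The tumour suppressor mean rested on Cdkn2a: without it the list averaged -0.003, and the median of its members was 0.005. The oncogenes lay above the tumour suppressors by 0.18 ± 0.12 in 11 of 11 cultures (exact permutation, adjusted p = 0.000977, the smallest 11 cultures allow), and by 0.06 ± 0.10 in 9 of 11 without Cdkn2a, Myc and Mdm2 (adjusted p = 0.043), an exclusion chosen after the values were seen.

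Genes recurrently lost in human bladder cancer averaged -0.28 ± 0.15 (SD, n = 11, exact sign-flip permutation test, adjusted p = 0.0044, below 0 in 11 of 11), and -0.15 without Cdkn2a (exact permutation p = 0.000977). Of 18 measured members 8 were lost and 1 gained, and 9 and 1 adjusted over the list alone. Mtap, next to Cdkn2a, was lost at -0.39 (limma adjusted p = 0.0096), Pde4d at -0.35 (0.0077) and Brinp1 at -0.45 (0.0096), while Notch1 was gained at 0.24 (0.027). Mtap lay in no deep deletion, and its mean was near that of the whole of chromosome 4 (-0.37). Cdkn2a, Mtap, Brinp1 and Arid1a (-0.31) all lie on that chromosome, so their losses are not independent. The list was not tested without all of them. Genes gained in human bladder cancer averaged 0.11 ± 0.21 and did not pass (exact permutation, adjusted p = 0.121), or 0.02 without Myc and Mdm2, but passed with another background correction (0.19, adjusted p = 0.005), with 3 of 21 members gained and 1, Ccnd1, lost, and 0 adjusted over the list alone. Genes lost in human kidney cancer averaged -0.24 ± 0.17 (exact permutation, adjusted p = 0.012), with 8 of 17 members lost and 0 gained, and 8 and 1 adjusted over the list alone; without Cdkn2a the mean was -0.10, and the members' median was 0.005. They included Ptprd, Pbrm1 at -0.40 and Setd2 at -0.23, chromatin regulators. The lost members Cdkn2a, Ptprd, Sdhb (-0.37) and Arid1a (-0.31) lie on chromosome 4, itself lost, so their losses are not independent. The list was not tested without all of them. Genes gained in human kidney cancer averaged 0.12 ± 0.17 (exact permutation, adjusted p = 0.032), of which Myc and Egfr (0.21) passed singly among 13, and 0 adjusted over the list alone. Without Myc that list averaged 0.04 and did not pass (exact permutation, adjusted p = 0.315). The gain lists lay above the loss lists by 0.39 ± 0.24 for bladder and 0.36 ± 0.16 for kidney cancer, in 11 of 11 cultures each (exact permutation, adjusted p = 0.000977 for both). The differences rested largely on Cdkn2a, Myc and Mdm2: without them, a test chosen after the values were seen, the differences were 0.17 ± 0.22 (exact permutation, adjusted p = 0.0065) and 0.14 ± 0.12 (adjusted p = 0.0039), each above 0 in 10 of 11 cultures.

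Genes of epithelial identity averaged 0.11 ± 0.10 (SD, n = 11, exact sign-flip permutation test, adjusted p = 0.0044, above 0 in 11 of 11). This mean includes Cldn7 (-0.52), measured on 10 arrays. Of the 14 members measured on all arrays 6 were gained and 1 lost, and 7 and 2 adjusted over the list alone. Krt18 was gained at 0.33 (limma adjusted p = 0.018) and Ovol1 at 0.43 (0.0079), while the splicing regulator gene Esrp1 was lost at -0.45 (0.012). Krt5 (0.33), Krt8 and Krt18 lie close together on chromosome 15 (starts 101767674 to 102091175), so their gains are not independent. Mesenchymal genes averaged -0.02 ± 0.11 (exact permutation, adjusted p = 0.533), although the members' median was 0.10. The list passed in either direction under some settings, at 0.04 with another background correction (adjusted p = 0.012), -0.05 without kidney F1G (0.013) and -0.05 without the 3 noisy arrays (0.042). Of 17 members 3 were lost, Twist1, Zeb1 and Cdh2 (-0.24), and 2 gained, the fibronectin gene Fn1 (0.29) and Col1a1 (0.32), with the same counts adjusted over the list alone. The mesenchymal genes lay below the epithelial genes by -0.13 ± 0.07 in 11 of 11 cultures (exact permutation, adjusted p = 0.000977). Genes of mitosis and the centrosome averaged 0.07 ± 0.08 (exact permutation, adjusted p = 0.032), with 3 of 18 gained and 1 lost, the checkpoint kinase gene Ttk at -0.43 (limma adjusted p = 0.0048), and the same counts adjusted over the list alone. These are DNA copy numbers and say nothing of expression. Density centring ended the calls of the oncogenes (adjusted p = 0.271), epithelial genes (0.271), human kidney gain genes (0.271) and mitosis genes (0.594), while the 4 differences between lists were unaffected by centring. The human kidney gain, mitosis and tumour suppressor calls ended when any 1 of 6, 6 and 8 single cultures was left out, and the human kidney gain (adjusted p = 0.060) and mitosis (0.109) calls also ended without the 3 noisy arrays. With dye as a block each list kept its side of the threshold. No list differed between the tissues (exact permutation, lowest adjusted p = 0.506, human kidney gain genes, 0.23 ± 0.20 in 5 bladder and 0.03 ± 0.06 in 6 kidney cultures, and 0.19 higher in bladder with dye as a block).

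Small regions of high-level change were sought as segments of at least 3 probes with a mean of at least 1 or at most -1. Myc and its neighbour Pvt1 lay in an amplicon in bladder M1C (chromosome 15, 60024720 to 63966286, 18 probes, mean 3.67) and bladder M2C (61966032 to 62248262, 7 probes, mean 4.43). Mdm2 was amplified in bladder M1I (chromosome 10, 117252305 to 117430402, 10 probes, 5.23) with a separate amplicon over Cand1 (118693434 to 118906468, 5 probes, 5.37), and in bladder F1G within 115153933 to 119979997 (94 probes, 1.84). Kidney M2G carried an amplicon on chromosome 9 (6893031 to 8256345, 54 probes, 4.32) with the apoptosis inhibitor genes Birc2 and Birc3, the Hippo pathway effector gene Yap1 and a cluster of matrix metalloproteinase genes, and another over the forkhead gene Foxa2 on chromosome 2 (147471175 to 148913724, 29 probes, 3.94). The probes of Birc2 differed by up to 4.21 on an array. Bladder M2C had 4 amplicons on chromosome 2, of which the one with Bcl2l1 and Tpx2 averaged 1.40 over 67 probes, and kidney F1B had 3 on chromosome 19 with means of 1.76 to 1.86. Stk11 lay in an 8-probe region of bladder M1I at 1.14. Coordinates are those of the array files, whose genome build is not given in the sources used here.

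Deep deletions over Cdkn2a spanned 88274647 to 88347828 on chromosome 4 in bladder F2G (4 probes, -5.19), kidney F1G (-3.90), kidney M2C (-5.00) and kidney M2G (-5.00), and 88274647 to 88284316 in bladder F1G (3 probes, -5.26). Between 1 and 3 of these probes were not well above background in the culture DNA of bladder F1G and the 3 kidney cultures, so the depth there is a bound. Bladder F1G also had a deletion over Ugcg and Ptbp3 on chromosome 4 (6 probes, -4.31, a bound, since 3 probes were not well above background), and a 14.1 megabase region of chromosome 7 with Fgfr2 averaged -1.01 over 345 probes. Kidney F1G had a deletion over Pard3 and Nrp1 on chromosome 8 (9 probes, -2.75, likewise a bound for 3 probes, on a noisy array). In all, the 11 arrays gave 45 amplifications and 128 deep deletions, of which 24 and 22 had at least 5 probes; 127 of the 173 had only 3 or 4. Without the 3 noisy arrays 34 and 91 were left. The counts and their balance depended on the processing: there were 97 amplifications and 52 deep deletions with another background correction, and 28 and 52 with a stricter segmentation threshold.

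Mdm2 or Myc amplification or a deep Cdkn2a deletion was present in 8 of 11 cultures, 5 of 5 bladder and 3 of 6 kidney, a combination chosen after its values were seen (Fisher's exact test, two-sided, p = 0.182). The X chromosome check did not bear out the label of kidney M2C, and with its dyes turned 7 cultures would be left. That turn would place its Cdkn2a loss in the normal liver DNA. With all 6 Cy5 arrays turned 3 would be left and the Cdkn2a mean would be -0.02 (limma adjusted p = 0.993). Myc amplification was found in 2 of 5 bladder and 0 of 6 kidney cultures (exact p = 0.182), as was Mdm2 amplification, and deep Cdkn2a deletion in 2 of 5 and 3 of 6 (exact p = 1). On the second arrays the Myc amplicon of bladder M2C at passage 59 averaged 4.19 over 126 probes, and the chromosome 9 amplicon of kidney M2G at passage 35 averaged 4.37 over 180 probes. The 4 amplicons of bladder M2C on chromosome 2 did not recur at that level: on the shared probes they averaged 0.43 to 0.63 at passage 59.

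The burden of change was similar in size but was not shown to be equal. Bladder cultures had 9 ± 3.54 chromosomes past 0.2 (SD, n = 5) and kidney cultures 8.83 ± 1.47 (n = 6), a difference of 0.167 (exact permutation p = 1), or -1.25 within the Cy5 arrays, 1 within the Cy3 arrays and -0.184 with dye as a block. The share of probes in altered segments was 53.3% ± 10.4 in bladder and 45.5% ± 9.24 in kidney cultures (exact permutation p = 0.214), with differences of 5.35 and 3.63 percentage points within the Cy5 and Cy3 arrays and 4.54 with dye as a block. Both measures fell with the noise of the array over the 11 cultures, with Pearson's r = -0.74 (permutation p = 0.0087, adjusted 0.011) and Spearman's rho = -0.64 (permutation p = 0.039) for chromosomes, and r = -0.73 (permutation p = 0.011, adjusted 0.011) and rho = -0.54 (permutation p = 0.095) for altered probes. Without the 2 arrays farthest from the median noise r was -0.65 and -0.72.

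Passages fell into 2 clusters, 5 kidney cultures at 35 to 41 and the 5 bladder cultures with kidney M2C at 53 to 67, so no pooled correlation is given. Among the 6 later cultures the number of changed chromosomes fell with passage (r = -0.95, exact permutation p = 0.0056, adjusted 0.011 over 2 relations, rho = -0.90, exact p = 0.028), and r was -0.81 over the 4 cultures left without the 2 farthest from the median passage. The relation was not stable: r was 0.19 with another background correction, -0.20 with density centring and 0.47 with a call at 0.1, and without the noisy array of bladder M1C, the latest passage, r = -0.87 did not pass (exact p = 0.067). For the share of altered probes r was -0.63 (exact permutation p = 0.181) and rho -0.49 (exact p = 0.333), and r was -0.18 over the 4 cultures.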

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

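All tests of explanations in this part were chosen after the result was seen, except the density centring of the X chromosome and the bin correlation of the bladder M2C arrays, whose spread over chromosomes was nevertheless added after the correlation was known.

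In 76 groups of cultures examined for a value far from the rest of its tissue, 9 were found, and chance gives about 1 in 20. Among bladder cultures the oncogene list of F2G stood at 0.042, with the others between 0.15 and 0.18. Among kidney cultures chromosome 5 of F2G stood at 0.70 (others 0.17 to 0.32) and chromosome 18 of M2C at -0.42 (others -0.14 to -0.08). The Myc probe of kidney F1G stood at -1.61 (others 0.01 to 0.91), and Zeb1 of kidney M2C at -1.15 (others -0.33 to -0.08). The list of genes gained in human bladder cancer reached 0.54 in kidney M2G (others -0.16 to 0.03), the culture with the amplicon over Birc3 and Yap1, both on that list. In kidney F1G the epithelial list reached 0.34 (others 0.02 to 0.14), the mesenchymal list 0.28 (others -0.09 to -0.03) and the number of changed chromosomes was 6 (others 9 to 10). Kidney F1G and M2C are 2 of the 3 noisy arrays.

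The larger design carries probes of the Y chromosome, which no comparison used. Their median was -2.90 over 593 probes in bladder M2C at passage 59 and -5.23 over 592 probes in kidney M2G at passage 35, both male cultures against a male reference. In kidney M2G 201 of 599 Y spots were not well above background in the culture DNA, so the depth there is a bound.

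The X chromosome of the male kidney culture M1C averaged -0.72, the lowest of the 11 cultures. A reference of the other sex was argued against, since X minus autosomes in the reference channel was -0.95, within the range of the other male references (-0.97 to -0.86) and far from the female ones (-0.05 to -0.03). Centring was argued against too, since X was -0.76 with density centring. A loss of X in this culture may remain, as a hypothesis found and tested on the same array, and a mislabelled culture was not tested.

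Of the 173 high-level regions 127 had 3 or 4 probes, and 125 of these could be set against the other arrays. Single-probe dye bias was argued against: the probes lay on the other side of their chromosome's value in the arrays of opposite dye in 45.6% of regions. An inherited difference between the cultured and the reference animals stays open, with 54.4% on the same side there. A probe pattern shared within a dye and scan series was put forward only after the dye bias test: in the other arrays of the series 79.2% lay on the same side, but so did 84.8% of regions of 5 or more probes. The mean in those arrays, signed by the region's direction, pointed the other way, 0.40 for the small regions and 0.11 for the larger ones. In the arrays of opposite dye the means were 0.07 and 0.08. The bounds were set with the values known, so this explanation stays open. Apart from the inherited difference no biological explanation was tested, and such small regions are best read with caution.

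Bladder culture M2C differed between its 2 arrays. Array noise was argued against, since 30 of 266 bins of 10 megabases differed by more than the largest difference (0.21) between the arrays of kidney M2G. The 2 such bins of chromosome 2 averaged 0.77 at passage 63 and 0.27 at passage 59, and the 2 of chromosome 7 0.04 and 1.03. More of the 30 lay spread along chromosomes 14 (10 bins, -0.59 and -0.29) and 10 (9 bins, -0.09 and 0.16). Another culture's DNA on an array could not be excluded: the bin correlation was 0.80 against at most 0.74 between different cultures, but this margin of 0.066 ran from -0.002 to 0.106 when 1 chromosome was left out. The arrays shared the Myc amplicon (4.43 and 4.30) and a deletion on chromosome 7 (-1.62 and -1.69), a comparison made after those values were seen, although bladder M1C also had the Myc amplicon and stood at -0.97 at that deletion. A change between passages stays open and was not tested.

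For the number of genes gained or lost over all cultures random signs of the cultures were argued against. Of 100 sign flips only the real one gave as many as 5100 genes (1 of 100), and the highest other gave 2. At an unadjusted p under 0.05 the real signs gave 7195 genes and the highest other 4701. Sign flips cannot tell a copy change from a probe bias shared by the arrays. For bladder against kidney the real split gave 0 genes, so all 100 of 100 regroupings gave as many by construction and this count decides nothing; the highest other gave 24. At an unadjusted p under 0.05, 41 of 100 gave as many as the real 720, so chance was not excluded.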

How the results depend on the processing

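The noisy-array exclusion, the dye block on the gene lists and on the number of changed chromosomes, the lists without Cdkn2a, Myc and Mdm2, and the turned dyes for the cultures with a change in these genes were tests chosen after the data were seen.

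Of the 13 called chromosomes 11 kept direction and call in every setting except Cy3 as culture dye throughout. The exceptions were chromosome 7 with normexp (-0.08, adjusted p = 0.063), and chromosome 10 with density centring (adjusted p = 0.18) and without bladder F1G, F2G, M1C, M1I or kidney F1B, F2G, M1C (adjusted p up to 0.081). Chromosome 6 passed as lost with density centring (-0.056, adjusted p = 0.0065), and chromosome 1 as gained with dye as a block (0.096), without bladder M1C (0.12) and without the noisy arrays (0.15). Leaving out 1 culture gave 5 to 6 gained and 7 lost chromosomes, 0 between the sexes, and 0 to 2 between the tissues, the 2 without bladder M1I. Between tissues normexp gave 1, density centring 3 and the second arrays 2 chromosomes. The cause was not tested for these or the values that follow, unless stated.

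Genes gained ran from 1826 (without bladder F2G) to 3029 and lost from 1640 (without bladder F2G) to 3057 over the left-out cultures. Genes gained and lost were 4254 and 4043 with array weights, 3921 gained without the 3 noisy arrays, 1541 gained with density centring, 1467 lost with normexp, and 0 and 6 within Cy5, which holds the 3 noisy arrays (the smaller Cy3 set gave 3193 and 3231). Between tissues 0 genes passed in all 25 alternatives.

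Amplifications and deep deletions numbered 97 and 52 with normexp, 83 and 269 at segmentation threshold 4, 28 and 52 at threshold 7, and 29 and 55 with at least 5 probes; the second arrays gave 245 deep deletions, having more probes.

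The bladder minus kidney number of changed chromosomes was -1.57 with normexp, -0.033 with the second arrays, -1.63 with a call at 0.3 and -0.184 with dye as a block, and ran from -0.833 to 1.42 over left-out cultures, negative without bladder F1G, F2G, M1I or kidney F1G. The difference in altered probes was -1.002 with normexp, -3.95 with segments at 0.3, and 4.70 to 11.3 over left-out cultures. For passage r was 0.19 with normexp, -0.20 with density centring, 0.47 with a call at 0.1 and -0.88 with a call at 0.3, and ran from -0.99 to -0.87 over left-out cultures, the last without bladder M1C.

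With normexp the tumour suppressors stood at 0.022 (adjusted p = 0.425) and the mesenchymal list passed as gained at 0.037 (adjusted p = 0.012), while it passed as lost without kidney F1G (-0.054) and without the noisy arrays (-0.048). Less Cdkn2a, Myc and Mdm2 the list calls of tumour suppressors and human kidney gain ended, and the list differences passed. The 4 list differences kept direction and call in all but the Cy3 setting; over left-out cultures they were 0.16 to 0.20 (oncogenes minus tumour suppressors), 0.33 to 0.42 (bladder), 0.33 to 0.38 (kidney) and -0.14 to -0.12 (mesenchymal minus epithelial). Among genes Myc lost its call without bladder M1C, M2C or kidney F1B, F2G, M2C, M2G (0.91 to 1.21), and Dcc, Ccnd1 and Zeb1 lost theirs without the noisy arrays (-0.23, -0.31 and -0.15). With normexp Myc (1.24) and Ccnd1 (-0.20), and with the second arrays Dcc (-0.55), Ccnd1 (-0.44) and Zeb1 (-0.31), also lost theirs.

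With Cy3 as culture dye on every array, which turns the 6 Cy5 arrays and goes against the kidney M2G check and the X chromosome check on 5 of the 6, 0 chromosomes were gained and 0 lost, 10 genes gained and 1 lost, and there were 106 amplifications and 67 deep deletions, with a Myc, Mdm2 or Cdkn2a change in 3 cultures. Cdkn2a fell to -0.025 and Myc to 0.054. The turned signs reversed chromosomes 4 (0.0023), 9 (0.028), 12 (0.013), 18 (0.043) and 19 (-0.073); Stk11 (-0.24), Mad1l1 (-0.044), Espl1 (-0.083), Krt8 (-0.13), Cdh1 (-0.22), Vim (-0.10), Ptprd (0.12), Twist1 (0.35), Dcc (0.44), Ccnd1 (0.52) and Zeb1 (0.19); and the lists of oncogenes (-0.0066), human bladder gain (-0.028) and loss (0.016), human kidney loss (0.0044) and mitosis (-0.017). The list differences became -0.0055, -0.043, 0.036 and -0.045 in the order above.

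The 4 culture codes found in both tissues did not pair the samples by their values: deviations from the tissue means correlated at 0.008 (F1G), 0.51 (F2G), -0.43 (M1C) and 0.014 (M2C), and 1 bladder culture correlated best with its own code. Whether a code marks 1 animal cannot be told from this, since changes acquired separately in each culture need not correlate. With this replicate block 0 chromosomes and 0 genes differed between tissues, where the exact test cannot go below 0.125. The gene fit with the block took its mean at code F1G alone and not over the cultures. Its 0 genes gained and 0 lost therefore cannot be set against the 655 and 577 on the same 8 arrays without it, and do not show an effect of the block. Signal over background was 4.92 or higher on every array.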

Other observations

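No test was run for this part, and its items were chosen after their values were seen.

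Arrays of bladder M1C and kidney M2C, both noisy and of the Cy5 series, had the highest correlation of any pair of the same dye over all probes, 0.83, and 0.91 after the local level was removed. Some named genes were close on both, such as Dcc at -2.21 in bladder M1C and -2.11 in kidney M2C and Zeb1 at -1.08 and -1.15, while Cdkn2a stood at 0.07 and -5.25 and Myc at 4.91 and 0.91.

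Bladder M1C and bladder F1G each had a small amplified region at 76 megabases of chromosome 15, apart from Myc, covering Mapk15 and Fam83h (76020372 to 76060662, 5 probes, 3.25, and 76049078 to 76123310, 7 probes, 1.21). Kidney F1B carried amplicons on chromosome 19 at 43159876 to 45242068 with Chuk, a kinase gene of the NF-kappa-B pathway (75 probes, 1.85), and at 54638557 to 55989531 with the Wnt pathway gene Tcf7l2 (25 probes, 1.86), on a chromosome gained in all 6 kidney cultures.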
